A study of Drosophila melanogaster with 32 samples.

How the data were processed

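Gene expression was measured in whole adult Drosophila melanogaster females on 32 Affymetrix expression arrays. The flies came from 8 laboratory populations derived from the LHM base stock, an outbred laboratory population. Of these, 4 had evolved under enforced monogamy (Mono1 to Mono4) and 4 under the usual promiscuous mating (Prom1 to Prom4), for 46 generations per the labels. Females of every population were mated to males of their own population or to males of the population of the same number from the opposite regime. They were frozen 6 h after mating. Each of the 16 crosses had 2 biological replicates, 1 in each of 2 batches, which gave 4 groups of 8 arrays. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns and labelled with biotin by in vitro transcription.

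The deposited values are log2 expression values, 1 per probe set and array. RMA and the affy package are named in the submitters' processing notes, without versions. RMA corrects background, normalizes arrays to a shared distribution of intensities and summarises each probe set on the log2 scale, so a change shared by most transcripts would be removed. Whether all arrays were normalized in 1 run is not given in the sources used here. Array medians lay between 5.41 and 5.50 and values between 2.27 and 14.80. No background level is held for each probe set, so low values were not called absent, and the number of arrays limits the precision.

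The table held 18952 probe sets, of which 183 array controls were left out and 18769 were tested. A probe set was named from the platform annotation where that gave 1 gene. This applied to 13646 probe sets, while 402 had several genes and 4721 had none named here. Of those with 1 gene, 13543 were matched by gene identifier to the table of RefSeq genes of the assembly Release 6 plus ISO1 MT, with 0 symbols updated, and 103 were not matched and kept their name. That table was used only for symbols, chromosome arms and gene order. A gene with several probe sets was represented by the one with the highest mean, which left 11981 genes. One list symbol, don, matched another gene through a synonym and was left out.

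Tests used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. For the female regime, the 4 arrays of each female population were averaged, and 4 promiscuous populations were compared with 4 monogamous ones. The populations, not the arrays, were the replicates of a regime. Each population mean held both batches and both male regimes equally. For the male regime, the replicates of each cross were averaged to 16 cross means, with female population as a fixed block, so that the contrast was the mean of 8 differences within female populations (6 residual degrees of freedom). The same fit gave the interaction, which is the male difference in promiscuous females minus that in monogamous females, and the male difference within each female regime. Own population and own regime cannot be separated by this interaction. Differences among populations of a regime were tested by a moderated F test on all 32 arrays, with the 16 crosses and batch as terms and 15 residual degrees of freedom. The same fit gave the difference between batches. A female population always met males of the same number, so the female and male populations of a number were not separated. For the same reason the 8 male differences rest on 4 pairs of male populations, each met by a Mono and a Prom female population, and the male fit takes the 8 as independent.

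Genes were named by a rule set before the data were examined. For each regime comparison it took the 12 genes with the largest change among those passing, and, with fewer than 5 passing in a direction, the genes with the lowest unadjusted p up to 5 per direction. For populations within a regime it took the 10 passing genes with the widest range of population means. For each gene list it took up to 4 members with the lowest p. Genes named outside this rule are said to have been chosen after their values were seen.

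The 28 gene lists were also fixed before the data were examined. They covered antimicrobial peptides, immune recognition and signalling, Bomanins and other immune-induced peptides, Turandot stress peptides, yolk with vitelline membrane and chorion, germline and oogenesis, ovulation and octopamine, and the sex peptide response. They also covered spermatheca and female tract secretion, digestive trypsins, juvenile hormone, ecdysone, insulin and TOR, lipid and carbohydrate metabolism, odorant and gustatory receptors, odorant-binding proteins, cytochrome P450s and glutathione transferases. The remaining lists were phototransduction, circadian clock, heat shock and chaperones, ribosomal proteins, oxidative phosphorylation, muscle, neuronal, male accessory gland, testis, and cuticle proteins. Lists held only genes with a named probe set, so several were cut. Bomanins and other induced peptides kept 9 genes from 25 symbols, some of them synonyms, and antimicrobial peptides 12 from 21. Heat shock kept 9 from 21, without Hsp70 genes, and phototransduction 17 from 27, without ninaE. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, and again with an estimated correlation. An exact permutation test of each list's mean over populations and Fisher's exact test of the share of list genes differing between populations were added after the data were seen. A test of X linkage had been planned for at least 10 genes called for the female regime and was not run, since 0 were called. The X was tested instead among genes differing between populations, which was not planned.

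The fits were tested on simulated data in which 67, 67 and 66 of 18769 probe sets were changed by 1.5, 2 and 4 fold. For the female regime 97.0, 95.5 and 98.5% were recovered, with 8 false among 202 calls. For the male regime the shares were 98.5, 100 and 100%, with 10 false among 209. For the interaction they were 74.6, 98.5 and 100%, with 6 false among 188. For populations within a regime they were 89.6, 100 and 100%, with 12 false among 205. A simulated list of 30 genes changed 1.2 fold was called with an estimated correlation in all 3 regime comparisons (adjusted p = 5.04e-05, 1.98e-05 and 0.00207). It was also called at the preset correlation. There 1 of 27 unchanged lists was falsely called for the female regime and 0 for the male regime and the interaction. The simulations drew the noise of each gene independently, so they held no spread shared between genes, and those for populations held no other population difference. In each run all changed probe sets were changed at once, which loosens the adjusted threshold, so lone changes would be recovered less often. For the female regime of the real data 12 genes differed by over 1 log2 unit and 0 probe sets were called.

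The counts of the regime comparisons were recomputed under other settings chosen before the data were examined. These were a block for population number, no block for female population, all 32 arrays with female population as a random block or as independent replicates, and an intensity trend in the moderation. They further included a filter at a mean log2 value of 6, cyclic loess on the deposited values, each batch alone, a threshold of 0.10 and leaving out each female population in turn. For populations within a regime the filter, cyclic loess, the trend and leave-outs were run, and the batch count and the correlation of male effects were not recomputed. Lists were recomputed with an estimated correlation, with all probe sets of their genes and, for the female regime, with the block and leave-outs. Cyclic loess, single batches and, outside the female regime, leave-outs were added for lists after the data were seen. Male population means with population number as a block were planned for probe sets and added for lists after the data were seen. Further settings for the male difference within each female regime, leave-outs for its list means and a covariate for RNA quality were also added then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.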

Results

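Expression of 18769 probe sets was measured in whole mated females from 8 experimental populations of Drosophila melanogaster, 4 kept under monogamy and 4 under promiscuity. Each population gave females for 2 crosses, 1 with males of the same population and 1 with males of the opposite regime, and each cross had 1 array per batch. This gave 8 arrays in each of the 4 groups, which were monogamous females with monogamous or promiscuous males and promiscuous females with monogamous or promiscuous males. The design asked how expression 6 h after mating depended on the mating regime in which the female, and her mate, had evolved. Replicate arrays of a cross correlated at 0.996 to 0.998, and arrays of other populations in the same batch at 0.994 to 0.997. RNA quality differed by batch. The signal difference between the 3' and 5' ends of control transcripts was larger in batch 2 by 1.00 log2 units for actin, 0.40 for GAPDH and 0.93 for eIF-4a, in 16 of 16 crosses each. It did not separate female regimes (two-sided exact p = 0.457, 0.229 and 0.314) or male regimes (two-sided exact p = 0.297, 0.367 and 0.313). Batch itself changed 3717 probe sets (19.8%), 1921 of them higher and 1796 lower in batch 2.

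Females of the 4 promiscuous populations were compared with those of the 4 monogamous populations to ask what evolution under each regime had done to the mated female. Among the 5 genes with the lowest p in each direction, the largest differences were in Mal-B1, a maltase that splits dietary disaccharides, and Zip102B, a zinc transporter. Mal-B1 was lower in promiscuous females by -1.22 ± 0.24 log2 units (standard error, n = 4 populations per regime) and Zip102B by -1.08 ± 0.18. CG40485 (-0.87 ± 0.14), CG3609 (-0.32 ± 0.05) and CG5727 (-0.18 ± 0.03) were lower too. Higher in promiscuous females were CG33281 (+0.53 ± 0.10), wat (+0.33 ± 0.05), a fatty acyl-CoA reductase needed for gas filling of the tracheae, CG11550 (+0.29 ± 0.04), CG17167 (+0.28 ± 0.05) and Vago (+0.27 ± 0.04), a secreted peptide of the antiviral response.

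None of these 10 genes passed adjustment. For each of them the 4 promiscuous population means lay wholly to 1 side of the 4 monogamous ones. They were picked for a low p on these same means, so this separation adds no support. For a single gene fixed beforehand it would give a two-sided exact p of 0.0286, the smallest possible. The adjusted p was 0.480 for 7 of the genes, 0.520 for CG17167 and 0.578 for CG33281 and Mal-B1. With limma 0 of 18769 probe sets were called, and 1312 had an unadjusted p under 0.05 (748 higher and 564 lower in promiscuous females) against 938 expected by chance. All 10 kept their sign in both batches, although the batches make up the means they were picked on. Examples were Mal-B1 with -1.40 in batch 1 and -1.04 in batch 2, Zip102B with -1.21 and -0.96, and wat with 0.41 and 0.24. A second probe set of CG40485 went the other way (+0.19), while that of CG33281 went the same way (+0.45). With the 32 arrays treated as independent replicates 473 probe sets were called, and with female population as a random block 123, both in limma, and all 10 named genes passed in both.

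Genes of lipid and carbohydrate metabolism fell in promiscuous females by -0.19 log2 units on average (median -0.06), with 23 of 36 genes lower (camera adjusted p = 0.00185, adjusted p = 0.783 with an estimated correlation). Their list mean gave a two-sided exact p of 0.0286, the smallest possible with 4 against 4 populations, and 0.4 after adjustment over the 28 lists. Its leading members were Mal-B1, tobi (-0.84 ± 0.17), an alpha-glucosidase induced by dietary protein, and Desat1 (-0.19), which makes unsaturated fatty acids. These 3 passed when adjusted over the list alone, against 0 over all genes. The difference of the list was -0.20 in batch 1 and -0.18 in batch 2. It held all 10 maltase genes and tobi (11 genes, -0.58 on average), which carried most of its fall. The other genes of the list were not tested apart, so the result of the list is not separate from that of the maltases.

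Maltases were then examined as a group, 1 singled out after their values were seen. Of 10 maltase genes and tobi, 10 were lower in promiscuous females, by -0.58 log2 units on average (two-sided exact p = 0.0286, the smallest possible). Mal-A7 was lower by -0.77, Mal-A1 by -0.65, Mal-A4 by -0.50, Mal-A2 by -0.48, Mal-A3 by -0.46, Mal-B2 by -0.23 and Mal-A8 by -0.13, while Mal-A5 was higher by 0.14. Only Mal-B1 and tobi had all 4 promiscuous populations below all 4 monogamous ones. In Mal-A1, Mal-A2, Mal-A3, Mal-A4 and Mal-A7, Prom3 lay above Mono1, for example at 11.99 against 11.53 for Mal-A1. The mean of Mal-A6 was lower by -1.28, but this gene did not part by regime either. It was at 9.32 in Mono1, 8.65 in Prom1, 9.21 in Prom2 and 9.50 in Prom4 against 10.94 to 11.79 in the other 4 populations. The Mal-A genes lie together on arm 2R, Mal-B1 and Mal-B2 on 2L and tobi on 3R. The 8 Mal-A genes alone gave -0.51 (two-sided exact p = 0.0571), and Mal-B1, Mal-B2 and tobi gave -0.76 (two-sided exact p = 0.0286, the smallest possible).

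**Figure D1:**
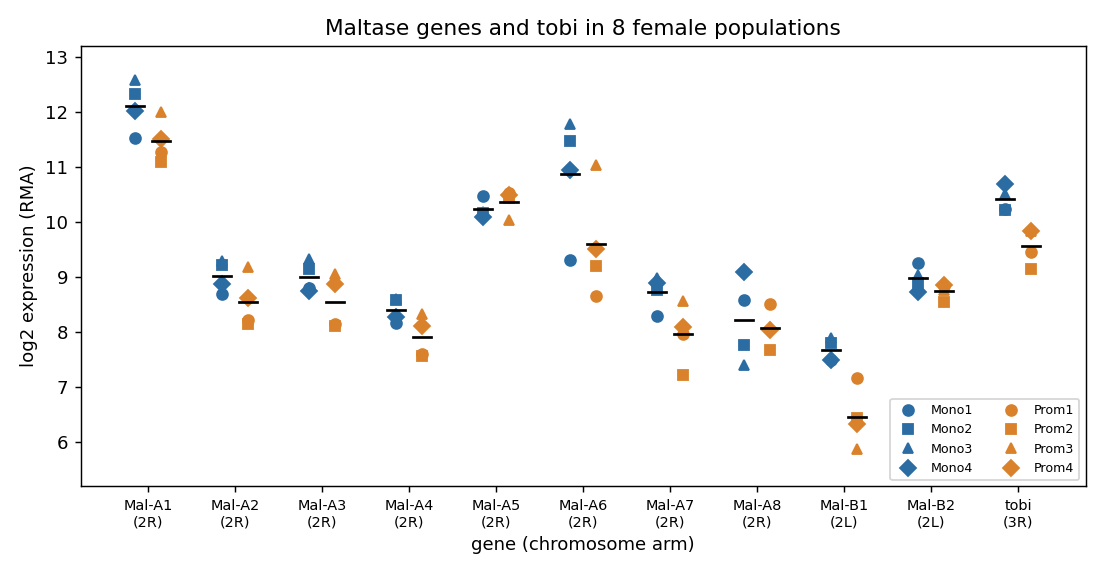
Mean log2 expression of the maltase genes and tobi in each of the 8 female populations (n = 4 arrays per point). Mal-B1 and tobi show 4 promiscuous populations below all 4 monogamous ones, while Mal-A6 is low in Mono1, Prom1, Prom2 and Prom4 and high in the other 4.

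Germline and oogenesis genes also fell in promiscuous females, by -0.05 on average with 24 of 33 lower (camera adjusted p = 0.00212, adjusted p = 0.783 with an estimated correlation). Examples were piwi (-0.26), which silences transposons in the germline, twe (-0.20), a meiotic phosphatase, CycE (-0.18), a driver of S phase, and orb (-0.13), which regulates translation in the oocyte. The list differed by -0.04 in batch 1, where it did not pass alone (adjusted p = 0.0909), and -0.06 in batch 2. Bomanins, short peptides made under Toll signalling, and other immune-induced peptides fell by -0.18 with 9 of 9 lower (camera adjusted p = 0.0420, adjusted p = 0.783 with an estimated correlation). Their value was -0.17 in batch 1 and -0.20 in batch 2, and neither batch passed alone (adjusted p = 0.0909 and 0.176). The call was also lost with cyclic loess at the same mean (-0.18, adjusted p = 0.0913), without Mono1 (-0.06, adjusted p = 0.675), without Prom2 (-0.18, adjusted p = 0.0941) or without Prom3 (-0.12, adjusted p = 0.186).

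Phototransduction genes rose by 0.07 in promiscuous females with 12 of 17 higher (camera adjusted p = 0.0420, adjusted p = 0.783 with an estimated correlation). The channel trpl (+0.18), the kinase inaC (+0.15) and the scaffold inaD (+0.12) were higher, while the G protein Galphaq was at -0.21 by 1 probe set and at +0.15 and -0.02 by 2 others. The list gave 0.08 in batch 1 and 0.06 in batch 2, and neither batch passed alone (adjusted p = 0.0909 and 0.176). Its call was also lost with cyclic loess (0.06, adjusted p = 0.0772), with all probe sets of its genes (0.04, adjusted p = 0.114), and without Mono1 (0.05, adjusted p = 0.135), Mono2 (0.04, adjusted p = 0.130), Prom3 (0.05, adjusted p = 0.204) or Prom4 (0.06, adjusted p = 0.0797). No member of the germline, Bomanin and phototransduction lists passed when adjusted over the list alone (0 in each). Nor did the means of these lists reach a two-sided exact p under 0.05. Only 2 of the 28 lists did so, lipid and carbohydrate metabolism and juvenile hormone.

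The other 24 lists did not pass for the female regime. Insulin and TOR genes were lower by -0.07 (adjusted p = 0.0913), with InR, the insulin receptor, at -0.30, sima at -0.23, Akt at -0.20 and rictor at -0.10, and the list passed without Prom3 (-0.08, adjusted p = 0.0388) and in batch 2 alone (-0.08, adjusted p = 0.0364). Yolk, vitelline membrane and chorion genes were higher by 0.10 (adjusted p = 0.150), and Vm32E, an eggshell protein, passed when adjusted over the list alone (+0.44, 1 gene, 0 over all genes). The yolk list passed without Mono2 (0.22, adjusted p = 0.00201) or Prom4 (0.14, adjusted p = 0.0379), and in batch 2 alone (0.11, adjusted p = 0.0343). Glutathione transferases were higher by 0.10 (adjusted p = 0.183), with GstE10 at +0.32. Spermatheca and female tract genes were higher by 0.14 (adjusted p = 0.183) and passed with a block for population number (0.14, adjusted p = 0.0435). Juvenile hormone genes were higher by 0.09 (adjusted p = 0.540), with jhamt, which makes the hormone, at +0.42 and Jhe, which degrades it, at +0.45. Their list mean gave a two-sided exact p of 0.0286, the smallest possible, and 0.4 after adjustment over the 28 lists. Sex peptide response genes were higher by 0.07 (adjusted p = 0.453), trypsins by 0.05 (adjusted p = 0.453), cytochrome P450s by 0.04 (adjusted p = 0.540) and odorant-binding proteins by 0.03 (adjusted p = 0.658). Antimicrobial peptides were lower by -0.11 (adjusted p = 0.451), Turandot stress peptides by -0.03 (adjusted p = 0.957), and ecdysone genes (adjusted p = 0.434) and cuticle proteins (adjusted p = 0.735) each by -0.02. Genes of oxidative phosphorylation (adjusted p = 0.198), neurons (adjusted p = 0.647) and immune recognition and signalling (adjusted p = 0.957) each had a mean of -0.01. Oxidative phosphorylation passed without Mono2 (-0.02, adjusted p = 0.0220) or Prom4 (-0.02, adjusted p = 0.0160). Heat shock (adjusted p = 0.934), ribosomal proteins (adjusted p = 0.957), muscle (adjusted p = 0.999) and testis transcripts (adjusted p = 0.957) each had a mean of 0.01. Means of clock genes (adjusted p = 0.540), receptors (adjusted p = 0.768), ovulation genes (adjusted p = 0.957) and male accessory gland transcripts (adjusted p = 0.939) were 0.00. For several of these small means the sign of the mean, the median and camera's direction differed, as for clock genes, of which 9 of 12 were higher.

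Mates were compared next, as the difference between females mated to promiscuous and to monogamous males within each of 8 female populations. After mating to promiscuous males, Bomanins and other immune-induced peptides fell by -0.28 log2 units, with 9 of 9 genes lower, and antimicrobial peptides fell by -0.21, with 10 of 12 lower. The first list held the Bomanins BomBc3 (-0.49) and BomT3 (-0.23) and the immune-induced IM33 (-0.15). The second held DptB, a diptericin against Gram-negative bacteria (-0.79), Drsl4 (-0.36) and Drsl5 (-0.13), of the drosomycin family. The list with Bomanins had a camera adjusted p of 6.14e-05 (adjusted p = 0.435 with an estimated correlation). Its mean had a two-sided exact p of 0.117 over 8 populations and 0.375 over the 4 pairs of male populations, 3 of which were lower. Antimicrobial peptides had a camera adjusted p of 0.000321 (adjusted p = 0.345 with an estimated correlation), and their mean over 8 populations had a two-sided exact p of 0.0312 (0.175 after adjustment over the 28 lists). The Mono and Prom females of a number met the same males, and over the 4 pairs of male populations the exact p of antimicrobial peptides was 0.125, the smallest possible. Drsl4 passed when adjusted over the list alone (1 gene, 0 over all genes) and was lower in 7 of 8 female populations.

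The immune differences were uneven across populations. The list with Bomanins gave -0.40 in batch 1 and -0.15 in batch 2, where it did not pass alone (adjusted p = 0.0512), and -0.18 without Mono1 or -0.17 without Prom1. Antimicrobial peptides gave -0.24 in batch 1 and -0.18 in batch 2, where they did not pass alone (adjusted p = 0.0809), and -0.14 without Mono1. Among immune recognition and signalling genes, PGRP-SB1, a peptidoglycan-binding protein, was at -0.49, and pirk, an inhibitor of the Imd pathway, at -0.24 and lower in 8 of 8 populations. That list did not pass (-0.04, adjusted p = 0.137), except with cyclic loess (-0.06, adjusted p = 0.0167) and without Mono3 (-0.06, adjusted p = 0.0118).

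Digestive trypsins and related proteases fell by -0.05 after mating to promiscuous males, with 21 of 27 lower (camera adjusted p = 2.75e-05, adjusted p = 0.345 with an estimated correlation). Examples were Ser7 (-0.13), Jon99Ci (-0.10) and betaTry (-0.07), and the list gave -0.07 in batch 1 and -0.04 in batch 2. Its mean had a two-sided exact p of 0.25 over the 4 pairs of male populations, 3 of which were lower. Germline and oogenesis genes rose by 0.04, with 29 of 33 higher (camera adjusted p = 0.000321, adjusted p = 0.435 with an estimated correlation). They included ovo (+0.10), a transcription factor of the female germline, BicD (+0.09), which transports messages into the oocyte, bcd (+0.08), the maternal anterior determinant, and piwi (+0.08). The germline difference was 0.05 in batch 1 and 0.04 in batch 2, with a two-sided exact p of 0.0312 over 8 populations (0.175 after adjustment) and 0.125, the smallest possible, over 4 pairs of male populations. Bright genes in general (mean log2 of at least 6) rose by 0.01 on average, with 35.7% of 7262 lower. Of the germline genes 32 of 33 were this bright, and of the muscle genes 20 of 20.

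Muscle genes rose by 0.04, with 16 of 20 higher (camera adjusted p = 0.00678, adjusted p = 0.547 with an estimated correlation). The giant sarcomere proteins bt (+0.15) and sls (+0.21) passed when adjusted over the list alone (2 genes, 0 over all genes), and Prm, paramyosin, was at +0.11. Muscle gave -0.03 in batch 1 (adjusted p = 0.271) and 0.11 in batch 2, 0.06 without Prom3, and lost its call without Prom2 (0.01, adjusted p = 0.270). The muscle mean had a two-sided exact p of 0.375 over the 4 pairs of male populations, 3 of which were higher. Genes of oxidative phosphorylation fell by -0.02, with 55 of 74 lower (camera adjusted p = 0.00122, adjusted p = 0.547 with an estimated correlation). They gave -0.04 in batch 1 and 0.00 in batch 2 (adjusted p = 0.953), and the call was lost without Prom3 (0.00, adjusted p = 0.434). Over the 4 pairs of male populations, 3 of which were lower, the two-sided exact p was 0.625.

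Lists whose genes mostly gave low signal in females fell slightly as well. Male accessory gland transcripts fell by -0.03 with 27 of 32 lower (camera adjusted p = 0.00145, adjusted p = 0.345 with an estimated correlation). Testis transcripts fell by -0.03 with 22 of 33 lower (camera adjusted p = 0.00626, adjusted p = 0.345 with an estimated correlation), and lost the call without Mono2 (-0.02, adjusted p = 0.0569) or with all probe sets of its genes (-0.02, adjusted p = 0.0507). Odorant and gustatory receptors fell by -0.02 with 112 of 166 lower (camera adjusted p = 0.000321, adjusted p = 0.428 with an estimated correlation), and by -0.03 without Mono4. Cuticle proteins fell by -0.02 with 72 of 105 lower (camera adjusted p = 0.00241, adjusted p = 0.345 with an estimated correlation). Over the 4 pairs of male populations each of these 4 lists had a two-sided exact p of 0.25. Cyclic loess ended the calls of accessory gland (-0.01, adjusted p = 0.239), testis (-0.01, adjusted p = 0.469), receptor (0.00, adjusted p = 0.730) and cuticle genes (-0.01, adjusted p = 0.367). In batch 2 alone receptors (-0.01, adjusted p = 0.0809), testis transcripts (-0.02, adjusted p = 0.0981) and cuticle proteins (-0.01, adjusted p = 0.285) did not pass. Genes with a mean log2 value under 5 outside these lists were lower by -0.02 on average, 64.9% of 3480 genes.

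**Figure D2:**
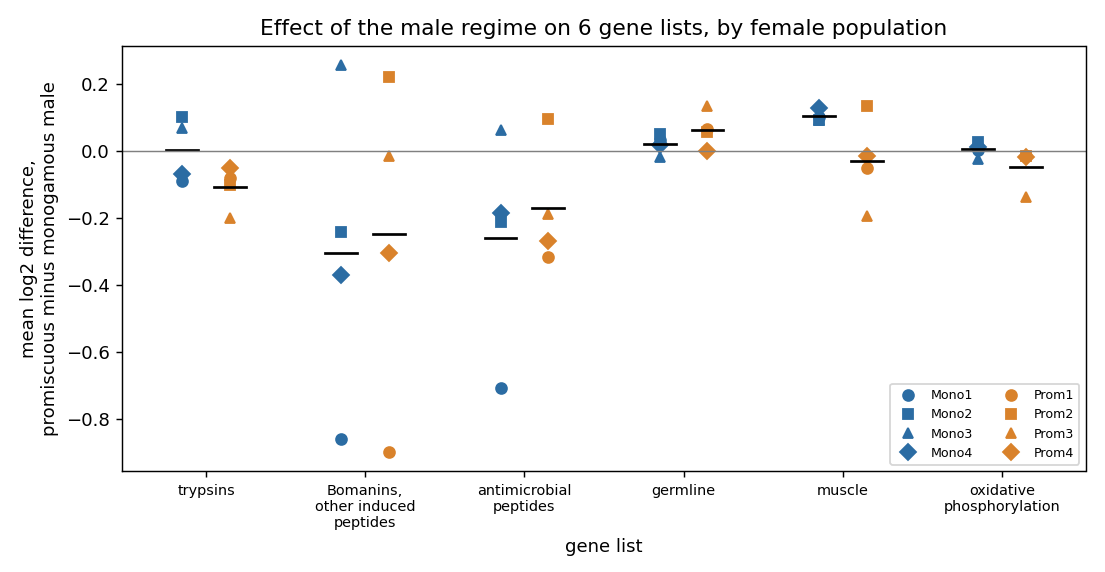
Mean log2 difference between females mated to promiscuous and to monogamous males, for 6 gene lists, by female population (1 point each), with the mean of 4 populations as a black bar. Antimicrobial peptides are lowest in Mono1 females and the list with Bomanins in Prom1 females (-0.90) and Mono1 females (-0.86), and muscle genes are higher on average in monogamous than in promiscuous females.

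The other 18 lists did not pass for the male regime (adjusted p from 0.0958 to 0.848). Heat shock genes and chaperones came closest, higher by 0.03 with 9 of 9 genes higher (adjusted p = 0.0958). Their mean was higher in 8 of 8 female populations (two-sided exact p = 0.00781, the smallest possible, 0.175 after adjustment, and 0.125 over 4 pairs of male populations). Clock genes were higher by 0.04 (two-sided exact p = 0.0234, 0.175 after adjustment, and 0.125 over 4 pairs of male populations), led by Pdp1, an activator in the clock, at +0.28 in 8 of 8 populations. Ovulation and octopamine genes were higher by 0.03 (two-sided exact p = 0.25 over 4 pairs of male populations). Of all 28 list means 5 had a two-sided exact p under 0.05 over 8 populations, and 0 did after adjustment. Besides immune recognition, 7 of the 18 passed in some setting. These were cytochrome P450s without Mono3 (-0.02, adjusted p = 0.0304) or Prom1 (-0.02, adjusted p = 0.0308), Turandot peptides without Mono4 (-0.10, adjusted p = 0.0243), ecdysone genes without Prom1 (0.03, adjusted p = 0.0473), and neuronal genes without Prom1 (0.04, adjusted p = 0.0350) or in batch 1 alone (0.05, adjusted p = 0.0145). Glutathione transferases passed without Prom4 (-0.02, adjusted p = 0.0119) or with cyclic loess (-0.02, adjusted p = 0.0384), and yolk genes (0.18, adjusted p = 0.0236) and odorant-binding proteins (-0.04, adjusted p = 0.00440) in batch 1 alone. For spermatheca and female tract genes the mean (+0.07) and median (-0.04) differed in sign. One gene in each of 4 uncalled lists passed when adjusted over the list alone (0 over all genes). These were Fcp3C at +0.79, a follicle cell protein, Nep2 at +0.11, a neprilysin peptidase, Ilp5 at -0.14, an insulin-like peptide, and GstE5 at -0.16, each in 8 of 8 populations.

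No single gene passed for the male regime. The lowest p on the higher side belonged to onecut, a homeobox transcription factor (+0.21 ± 0.03, standard error, n = 8 differences), bib, the channel protein big brain (+0.21 ± 0.03), Camta, a calmodulin-binding transcription activator (+0.19 ± 0.03), CG42540 (+0.16 ± 0.03) and RluA-1 (+0.14 ± 0.03). On the lower side were acs (-0.24 ± 0.04), ppk25, a sodium channel subunit of chemosensory neurons (-0.15 ± 0.03), CG7786 (-0.14 ± 0.03), CG10029 (-0.13 ± 0.03) and retinin, a protein of the corneal lens (-0.13 ± 0.03). All had an adjusted p of 0.402 and the same direction in 8 of 8 populations, except bib with 6 of 8. Other probe sets of CG42540 (-0.02 and 0.02) and of Camta (-0.10, -0.02 and -0.01) did not follow. With limma 0 of 18769 probe sets were called and 1977 had an unadjusted p under 0.05 (963 higher, 1014 lower), against 938 by chance.

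Whether the effect of the mate depended on the female's regime was tested as an interaction, which also separates mates of the female's own regime from others. Among the 4 lists that passed, muscle genes differed most. After mating to promiscuous males they were higher by 0.10 in monogamous females, with 0.09 to 0.13 in each population. In promiscuous females the mean was -0.03 but mixed, with -0.05 in Prom1, +0.13 in Prom2, -0.19 in Prom3 and -0.01 in Prom4, and it was +0.02 without Prom3 and -0.08 without Prom2. The difference was -0.13, with 19 of 20 genes lower (camera adjusted p = 3.24e-07, adjusted p = 0.765 with an estimated correlation). Obsc (-0.33), a giant sarcomere kinase, and bt (-0.27) passed when adjusted over the list alone (2 genes, 0 over all genes), although a second probe set of Obsc was at +0.18. The muscle difference was -0.16 in batch 1 and -0.11 in batch 2, and -0.08 without Prom3.

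After mating to promiscuous males, trypsins were lower by -0.11 in promiscuous females, in 4 of 4 populations. In monogamous females their mean was 0.00 over populations that went both ways (-0.09 in Mono1, +0.10 in Mono2, +0.07 in Mono3 and -0.07 in Mono4). The difference of -0.11, with 21 of 27 genes lower, had a camera adjusted p of 0.000576 (adjusted p = 0.765 with an estimated correlation). It was -0.14 in batch 1 and -0.08 in batch 2, and its leading members were Jon65Aii (-0.68), Jon99Ci (-0.25) and thetaTry (-0.21). Genes of oxidative phosphorylation differed by -0.05, with 66 of 74 lower (camera adjusted p = 7.68e-05, adjusted p = 0.765 with an estimated correlation), led by ND-B8 (-0.26), a subunit of complex I. They gave -0.10 in batch 1 and 0.00 in batch 2 (adjusted p = 0.953), and the call was lost without Prom3 (-0.02, adjusted p = 0.131). Phototransduction genes differed by -0.08, with 15 of 17 lower (camera adjusted p = 0.00616, adjusted p = 0.765 with an estimated correlation), among them rdgA (-0.22), a diacylglycerol kinase, and trpl (-0.17). They gave -0.17 in batch 1 and 0.00 in batch 2 (adjusted p = 0.927), and the call was lost without Prom1 (-0.08, adjusted p = 0.0564). For the interaction 0 of the 28 list means, the 4 called lists included, had a two-sided exact p under 0.05 (smallest 0.0571).

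Among single genes the interaction was clearest for GstD5, a glutathione transferase, and CG4830, which did not pass (adjusted p = 0.0807 each). With promiscuous instead of monogamous males, GstD5 was at -0.28 in monogamous and +0.32 in promiscuous females, a difference of 0.60 ± 0.07 (standard error, n = 4 populations per regime). CG4830 was at +0.17 and -0.31, a difference of -0.48 ± 0.06. GstD5 gave 0.97 in batch 1 and 0.24 in batch 2, while CG4830 gave -1.13 and +0.17. An intensity trend in limma called CG4830 (adjusted p = 0.0179). The other named genes had an adjusted p of 0.661. These were CG5770 (+0.77), CG31300 (+0.44), CG5245 (+0.27), CG12898 (+0.21), bib (-0.36), Sur, the sulfonylurea receptor (-0.34), CG14615 (-0.31) and CG17027 (-0.28).

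With limma 0 of 18769 probe sets were called for the interaction, and 1367 had an unadjusted p under 0.05 (629 higher, 738 lower). GstD5 and fru, the sex determination gene fruitless (-0.29), passed when adjusted over the list alone (1 gene each, 0 over all genes), although 6 other probe sets of fru lay between -0.08 and +0.10. The other 24 lists did not pass (adjusted p from 0.0540 to 0.989), among them spermatheca and female tract genes with a mean difference of -0.23 and a median of 0.01. The lowest of these belonged to germline and oogenesis genes (0.0540), which were called with opposite signs in the batches, at +0.14 in batch 1 (adjusted p = 1.25e-05) and -0.05 in batch 2 (adjusted p = 0.0456). They also passed without Mono2 (0.05, adjusted p = 0.0269), Mono4 (0.04, adjusted p = 0.0408) or Prom4 (0.07, adjusted p = 0.00108) and with cyclic loess (0.04, adjusted p = 0.0395). Within monogamous females alone the mate changed 0 probe sets in limma (1608 unadjusted, 866 higher and 742 lower, smallest adjusted p = 0.156). Within promiscuous females alone it changed 0 as well (1766 unadjusted, 908 higher and 858 lower, smallest adjusted p = 0.345). Across 11981 genes, which are not independent replicates, the mate's effects in the 2 female regimes correlated weakly (Pearson 0.0781, Spearman 0.0917). Of 35 splits of the populations into 4 and 4, 34 gave a Pearson correlation at least as high (median 0.190).

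Populations of the same regime differed strongly from each other. CG6765 had the widest range, from 3.42 in Mono1 to 8.81 in Mono2 (adjusted p = 2.88e-11), with 8.36 in Mono3 and 8.22 in Mono4. Cyp12d1-d, a mitochondrial cytochrome P450 linked to insecticide resistance, spanned 4.24 log2 units, from 4.29 in Mono3 to 8.54 in Mono1 (adjusted p = 2.21e-07), and Cyp4d21, another P450, spanned 3.25 (adjusted p = 4.79e-07). DptB ranged over 3.53 (adjusted p = 0.0149), with 10.54 in Mono1. Of the other genes with the widest ranges, CG34251 spanned 3.80 (adjusted p = 1.81e-07), Send2, a serine protease of the spermatheca, 3.58 (adjusted p = 0.0358), Spn38F, a serpin, 3.11 (adjusted p = 4.32e-07), RalGPS 3.07 (adjusted p = 1.24e-08), CG2772 3.02 (adjusted p = 4.73e-07) and CR44101 3.01 (adjusted p = 2.77e-07). Low ends such as 3.42 for CG6765 in Mono1, 2.95 for Spn38F in Mono1 and 3.80 for CG34251 in Prom1 were near or below the mean of the receptor list (3.69). Ranges that start at such low signal may be understated.

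**Figure D3:**
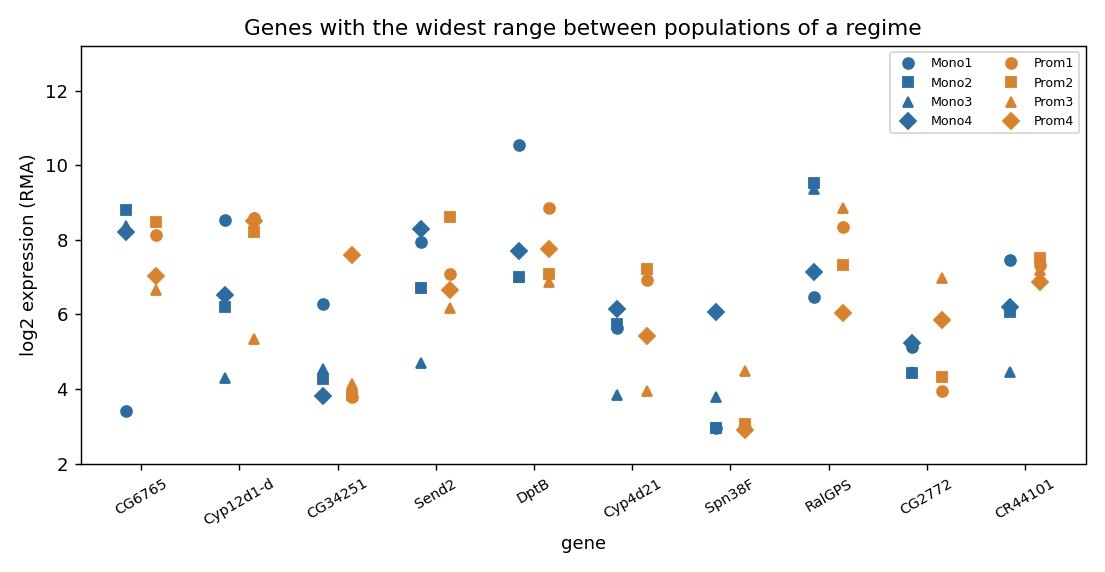
Mean log2 expression of the 10 genes with the widest range between populations of a regime, in each of the 8 female populations (n = 4 arrays per point). CG6765 is near 3.42 in Mono1 and above 6 in all other populations.

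In total 2572 of 18769 probe sets (13.7%) differed between populations of a regime, which covered 2083 of 11981 genes (17.4%). The range exceeded 2 fold for 243 of these genes, 4 fold for 46 and 8 fold for 10. Single populations carried much of several ranges. The range was 1.83 for CG6765 without Mono1, 2.47 for CG34251 without Prom4, 1.60 for Spn38F without Mono4, 1.88 for CG2772 without Prom3, and 1.75 without Mono1 or 1.40 without Mono3 for CR44101, all of which still passed. DptB lost its call without Mono1 (range 2.01, adjusted p = 0.343). Send2 lost its call without Mono3 (adjusted p = 0.311), Mono4 (adjusted p = 0.0729), Prom2 (adjusted p = 0.0904) or Prom3 (adjusted p = 0.0576).

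Detoxification and digestion genes stood out among those that differed between populations. Glutathione transferases did so for 26 of 36 genes (72.2%, Fisher's exact test, two-sided, adjusted p = 1.80e-11), cytochrome P450s for 41 of 85 (48.2%, exact adjusted p = 7.35e-10) and trypsins for 20 of 27 (74.1%, exact adjusted p = 1.40e-09). Lipid and carbohydrate genes differed for 21 of 36 (58.3%, exact adjusted p = 2.69e-07), spermatheca genes for 8 of 14 (57.1%, exact adjusted p = 0.00400), clock genes for 6 of 12 (exact adjusted p = 0.0341) and muscle genes for 8 of 20 (exact adjusted p = 0.0447). Receptors differed in only 8 of 166 genes (4.82%, exact adjusted p = 8.20e-06) and oxidative phosphorylation in 3 of 74 (4.05%, exact adjusted p = 0.00400). Among 7262 genes with a mean log2 of at least 6, of which 23.5% differed, muscle did not pass (exact adjusted p = 0.226), and receptors, with no gene at that level, could not be tested, so their low share was not separated from their low signal. Odorant-binding proteins (11 of 21, exact adjusted p = 0.0150) and, with few genes, ribosomal proteins (1 of 29, exact adjusted p = 0.0218) passed among these genes only. On the X chromosome 21.2% of 1200 such genes differed, against 26.1% on 2R, 24.5% on 2L, 24.1% on 3L, 21.8% on 3R and 19.0% of 42 genes on chromosome 4 (X against the rest, Fisher's exact test, two-sided, p = 0.0403). The test of the X was not planned and its p-value is unadjusted. Fisher's exact test counts genes as independent. Called genes were neighbours in 373 pairs against 287 expected, so the p-values of the lists and of the X may be too small.

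**Figure D4:**
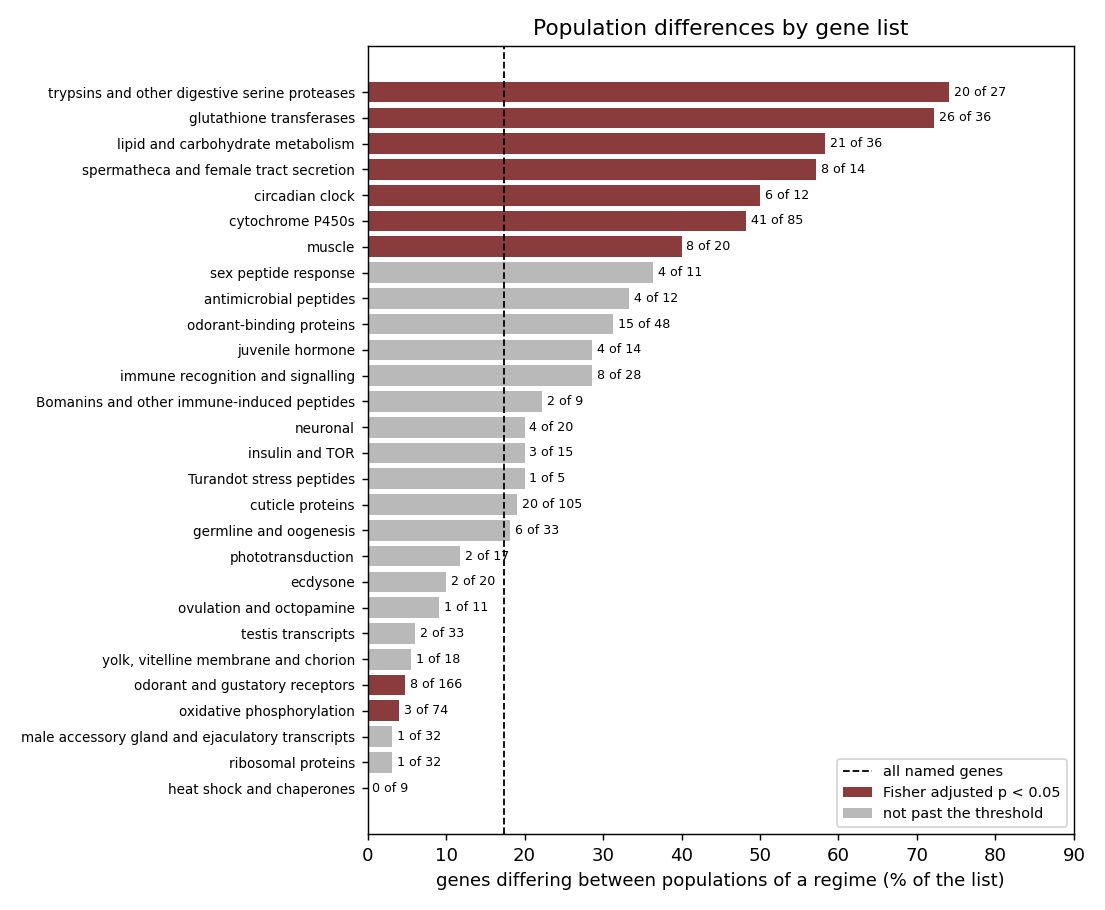
Percentage of the genes of each list that differed between populations of a regime (bars from 0), with the percentage over all named genes (17.4%) as a dashed line. Trypsins (74.1%) and glutathione transferases (72.2%) are highest.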

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

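Tests added only after the result was seen were those of bright second probe sets and of second probe sets for ranges above 1 log2 unit, of the absolute correlation of neighbouring genes and of exchanged population labels, and the fit with a covariate for RNA quality.

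Single populations stood apart from the other 3 of their regime, by a gap beyond the critical value of Dixon's test, in 13 of 192 groups examined, and chance gives about 1 in 20. That rate does not hold for the genes, which were picked for wide ranges or a low p on the same values. Population means of genes gave 7 of 40 groups and male differences of genes 2 of 40. Several such values were in genes that differed between populations. CG6765 was at 3.42 in Mono1 against 8.22 to 8.81 in the other monogamous populations, and Cyp12d1-d at 5.33 in Prom3 against 8.20 to 8.58. CG34251 was at 7.60 in Prom4 against 3.80 to 4.14, and Spn38F at 4.50 in Prom3 against 2.90 to 3.07. Among genes named for the regimes, wat was at 8.81 in Mono4 against 8.95 to 8.97, CG3609 at 10.24 in Prom1 against 10.28 to 10.29, and CG40485 at 6.54 in Prom1 against 6.11 to 6.17. Male differences stood apart for retinin in Prom3 females (-0.20 against -0.08 to -0.06) and for CG4830 in Prom4 females (-0.26 against -0.34 to -0.33).

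Gene lists stood apart in 4 of 112 groups, fewer than chance gives. The male difference of oxidative phosphorylation genes was -0.14 in Prom3 females against -0.02 to -0.01, that of Turandot peptides +0.0859 in Mono4 females against -0.16 to -0.12, and that of heat shock genes +0.0275 in Mono2 females against 0.01. Muscle genes in Prom4 females were 0.11 above the mean of the 8 populations, against -0.04 to -0.03 in the other promiscuous populations.

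The male effect differed between female regimes by an interaction test for 4 lists, which were muscle (-0.13), trypsins (-0.11), phototransduction (-0.0846) and oxidative phosphorylation (-0.0512). The calls rested on a preset correlation between genes. Chance could not be excluded for the number of lists, since 25 of 35 splits of the populations into 4 and 4 gave at least 4 lists and the highest other split gave 12. Nor was it excluded for single probe sets, where 1367 had an unadjusted p under 0.05, 2 of 35 splits gave as many and the highest other gave 1436.

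The differences between populations of a regime were beyond chance. With 100 shufflings of arrays among populations, the real one included, 1 gave as many called probe sets, with 2572 against 162 in the highest other. Differences between batches were beyond chance as well, with 3717 called, 1 of 100 as many and 185 in the highest other.

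The pattern that populations of a regime differed at many genes, often beside one another on the chromosome, was weighed against 3 technical explanations. A sequence variant under 1 probe set stayed open over all 173 called genes with a second probe set, whose median correlation over the 8 populations was 0.380, and over 15 of them with a range above 1 log2 unit (0.273), and was argued against only for 71 with a bright second probe set (0.722, compared with 0.247 in 261 uncalled genes). RNA quality stayed open too, since 86.8% of the called probe sets passed again with a covariate for it, but the covariate itself was called for 0 probe sets and so tested little. Labels exchanged between regimes stayed open as well, since an exchange of Mono1 and Prom3 would make the split with most calls, and the 84.6% of its called genes on 1 chromosome arm decide nothing, because a regime difference carried on that arm would lie there too. Adjacent called genes had a mean correlation of 0.0722 (0.00138 after shuffling, one-sided permutation p = 0.002) and a mean absolute correlation of 0.495 (0.348 after shuffling, one-sided permutation p = 0.001, the smallest possible), so chromosome segments that came to differ between the populations may account for part of the pattern, as a hypothesis.

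Splits other than by regime also called probe sets. Mono1, Prom1, Prom2 and Prom4 against the other 4 populations gave 32 called probe sets, and the next split gave 3. Of 26 genes with a known place in that split, 22 were on arm 2R (84.6%, against 20.4% of all genes, Fisher's exact test, two-sided, p = 3.87e-12). That test takes neighbouring genes as independent. The same split gave more than the regimes at an unadjusted p under 0.05 (1469 against 1312), with independent arrays (578 against 473) and with a random block (235 against 123). This split had many more calls than the real one, which had 0 (limma, 1312 at an unadjusted p under 0.05). It was the highest of 35 splits, and whether such a highest count is unusual was not tested. A shared segment of 2R or exchanged labels of Mono1 and Prom3 could each give it, so its cause stays open.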

How the results depend on the processing

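Tests chosen only after the data were seen were cyclic loess and single batches for lists, leave-outs for the lists of the male regime and interaction, male population means for lists, and other settings of the male difference within each female regime, with leave-outs for its lists. Counts of 0 called probe sets in limma held under the other settings run, with these exceptions. Treating 32 arrays as independent called 473 probe sets for the female regime, and female population as a random block 123, which by construction counts arrays besides populations. For the interaction a trend called 1, and a threshold of 0.10 called 2 by its looser limit. CG4830 was 0.17 in batch 2 only, and the cause was not tested. Without single populations, probe sets with an unadjusted p under 0.05 numbered 1000 to 1600 for the female regime, 1560 to 2299 for the male regime and 1081 to 1616 for the interaction, and called probe sets between populations 2108 to 2362.

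Called lists depended more on the settings, and apart from the estimated correlation the cause was not tested. An estimated correlation, which allows for shared spread, left 0 lists in all 3 comparisons. For the female regime loess left 2, batch 1 only 1, and leaving out single populations 2 to 5. For the male regime batch 2 only left 4, losing antimicrobial peptides, Bomanins and other induced peptides, receptors, oxidative phosphorylation, testis and cuticle, and leave-outs 9 to 13. For the interaction leave-outs gave 3 to 8. Muscle under the male regime was -0.0307 in batch 1 only. The interaction was 0.00442 for phototransduction and 0.00160 for oxidative phosphorylation in batch 2 only. Of the values of called lists 196 stayed past the threshold and 49 lost it, and of the values of named genes 570 stayed on their side, 5 lost the call and 21 gained it. Uncalled lists gained a call in at least 1 setting for 4 lists of the female regime, 8 of the male regime and 7 of the interaction.

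Population number as a replicate block gave 0 probe sets for the female regime (1363 unadjusted) and for the interaction (1243 unadjusted). It called 5 lists for the female regime instead of 4, the added 1 being spermatheca and female tract genes (adjusted p = 0.0435), and the cause was not tested. Male population means with that block gave 0 probe sets (1803 unadjusted) and 10 lists. Without a block for female population the male regime gave 0 (967 unadjusted) and the interaction 0 (557 unadjusted). Populations of a number shared mates, and their deviations had correlations of 0.129, 0.0707, 0.193 and 0.0238 for numbers 1 to 4, and 1 of these did not correlate best with its own number. No background per probe set was used here, so signal over background was not a limit that could be tested.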

Other observations

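Tests added only after the result was seen were those of the trypsin means, of the Mal-A and Mal-B1, Mal-B2 and tobi segments, of the matching of immune differences by male number, of swaps by male pair, of all maltases as a group, and of maltases in the split with most calls.

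Lower maltase expression in promiscuous females was weighed against a smaller share of gut tissue and a single chromosome segment. The digestive trypsins were not lower in promiscuous females (+0.05, two-sided exact p = 0.543). Their lowest promiscuous minus their highest monogamous population mean was -0.16 log2 units, against a difference of -0.58 for maltases. These values argue against a smaller gut share only as far as trypsins follow gut share, which was not tested. Of the trypsin genes 20 of 27 differed between populations of a regime, so they are an uneven gauge. The test chosen first, of maltases minus trypsins (-0.63), had a two-sided exact p of 0.0571. A segment over the Mal-A genes does not reach Mal-B1, Mal-B2 and tobi on other arms, but their difference (two-sided exact p = 0.0286, the smallest possible) decides nothing, since Mal-B1 and tobi were picked for being lower. For the Mal-A genes the segment stayed open, since 18 called genes nearby had a mean absolute correlation of 0.521 with them, against 0.352 elsewhere (499 of 11072 windows as high, one-sided permutation p = 0.0452), and since Mal-A6 (-2.14, limma adjusted p = 0.00933) and Mal-A5 (+0.35, adjusted p = 0.0204) were called with Mono1, Prom1, Prom2 and Prom4 set against the other populations, where 22 of 26 placed called genes lay on 2R. Evolution under the regime stays open against drift of the populations. With populations as replicates neither Mal-B1 nor tobi passed (limma adjusted p = 0.578 each). The maltases and tobi as a group had a two-sided exact p of 0.0286, but the group was singled out after its values were seen.

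Slightly lower gland, testis, receptor and cuticle lists after mating to promiscuous males were weighed against a shift shared by dim probe sets and against male RNA carried in the female. Compared with other dim genes (mean log2 under 5), 0 of 4 lists were called (camera, adjusted p from 0.245 to 0.962), and 64.9% of 3480 other dim genes were lower against 35.7% of 7262 bright ones. Dim gland genes fell further (-0.0376, 92.9% of 28 lower), as did dim testis genes (-0.0325, 70% of 30), against -0.0173 for other dim genes. A shift shared by dim probe sets may therefore account for the receptor and cuticle lists, and for at least part of the gland and testis lists. Less male RNA could not be told apart, since gland and testis lists did not separate from receptor and cuticle lists (two-sided exact p = 0.359, n = 8 differences).

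Over both batches the 21 immune peptides differed most with males of number 1, but not in batch 1 alone. After mating to promiscuous males they were lower by -0.77 in Mono1 females (-0.548 in batch 1 and -0.995 in batch 2) and by -0.57 in Prom1 females (-0.27 and -0.86). In Mono2 females they were at -0.22 and in Mono4 females at -0.26, with larger values in batch 1 (-0.60 and -0.71) that turned positive in batch 2 (+0.15 and +0.18). They were at +0.15 in Mono3 (0.11 and 0.18), +0.15 in Prom2 (-0.03 and 0.33), -0.11 in Prom3 (-0.09 and -0.14) and -0.28 in Prom4 females (-0.37 and -0.20). That males of a number may set the size of the difference is a hypothesis, and a matching of female populations by number gave an exact one-sided p of 0.125 over 24 matchings (smallest possible 0.0417), which leaves it open. Over all genes, male effects of the same number correlated at 0.0459 and of different numbers at 0.0173 (one-sided exact p = 0.333).

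Whether other splits of the populations gave results as large was counted for each regime comparison. For the female regime chance could not be excluded. Of 35 splits 2 gave at least 1312 probe sets with an unadjusted p under 0.05, with 1469 in the highest other, and 21 of 35 gave at least 4 lists, with 12 in the highest other. With independent arrays 2 of 35 gave at least 473 calls (578 in the highest other), and with a random block 2 of 35 gave at least 123 (235 in the highest other). Except for lists, the highest other was the same split each time, Mono1, Prom1, Prom2 and Prom4 against the rest. These counts rest on the same values, and an exchange of the labels of Mono1 and Prom3 was left open, so the cause of this split stays open. For the male regime 2 of 100 swaps of male labels within female populations gave at least 1977 probe sets at an unadjusted p under 0.05 (2272 in the highest other), which excludes chance only if the females of a number, which met the same males, count as independent. Swapped by male pair, the 8 swaps are too few for a share under 0.05, with 1977 against 1615 in the highest other (1 of 8 as large) for probe sets and 10 against 12 (3 of 8 as large) for lists. For lists chance was not excluded within female populations either, where 13 of 100 swaps gave at least 10 (13 in the highest other). Within monogamous females (1608, and 1686 in the highest other, 2 of 8 as large) and within promiscuous females (1766, and 1172 in the highest other, 1 of 8 as large) the 8 swaps are too few for a share under 0.05.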
